A study of Rattus norvegicus with 7 samples.

How the data were processed

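RNA from synovium of 7 male rats aged 3 months, 3 untreated and 4 injected with MIA in the right knee, was sequenced as 1 library per rat, made from 1.5 µg of RNA. Groups and replicate numbers were taken from the labels. The submitters' processing notes name HISAT2, HTSeq 0.11.2, DESeq2 1.26.0 and the rat genome build Rnor_6.0 and state no role for any of these tools. The deposited table gives, per the file headers, a count and an FPKM value per gene and library, and the counts were whole numbers. For the deposited FPKM values, per the file headers, no formula is stated; computed back from the values, they are counts per gene length and column total, with the same length in every library for 18593 of 18593 genes with a count in 2 or more libraries (tolerance 1e-09). The counts were used for the tests, and FPKM for the naming rule and 1 alternative. The strand setting, trimming and annotation release are not given in the sources used here, so counts of genes that overlap on opposite strands are uncertain, as are counts of genes with near-identical copies (class II RT1 genes, haemoglobins, myosin heavy chains, Amy1a, Ftl1). No coordinates are given, because the reference table at hand describes another build and served only to look up synonyms.

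The table held 20660 genes, 63 symbols on more than 1 line, 13 mitochondrially encoded genes and 0 identical count columns. Total counts were 15819900, 13870822 and 15251664 in control 2 to 4 and 15769573, 14119648, 15053696 and 16261089 in MIA 1 to 4. Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr with the group (14054 genes kept), TMM factors (0.801 to 0.902 in control and 1.06 to 1.23 in MIA libraries), and the quasi-likelihood F test with Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. The common biological coefficient of variation was 36.7%. CPM are counts relative to the TMM-scaled library size, given as mean ± SD, and log2 changes are MIA minus control ± SE. For edgeR fits this SE is derived from the test, as the absolute log2 change divided by the square root of F. It cannot be read where F is very small. On simulated data with 100 genes changed 2-fold and 100 changed 4-fold, 15% and 75% were called, 3.06% of the calls were false, 0 had the wrong direction, and 0 of 31 unchanged lists were called. Genes were drawn independently there, whereas the estimated correlation within the real lists reached 0.851, for oxidative phosphorylation. The 0 of 31 therefore does not vouch for the list test on these data.

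The lists, 14 of functions and 17 of cell types, held 607 distinct genes, of which 579 were matched by symbol, 4 by synonym and 24 not at all. Each was tested with camera of limma 3.58.1 on voom values (preset correlation 0.01, then an estimated correlation), with fry, and by its mean log2 CPM per library with an exact two-sided permutation over 35 assignments, adjusted over the 31 lists. Members were also adjusted over the list alone. Cell type lists describe transcripts of a mixed tissue and name no cells. The lists, the tests of genes and lists between the groups, the alternatives in processing except the stromal scaling, and the rule for naming genes were fixed before the data were examined; the closing section says which of its own tests were chosen later.

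Genes were named by this rule: the 7 largest rises and 7 largest falls by fitted log2 change among called genes whose groups do not overlap in any library, with a mean of at least 1 FPKM in at least 1 group and a proper symbol (not starting with LOC, RGD, AABR, AC, NEWGENE or ENSRNOG, and not a number followed by Rik); the 2 tested members with the smallest p of each function list; and the tested member with the smallest p of each cell type list. Other genes are said to have been chosen after their values were seen. For genes with no count in a group, folds are lower bounds against a floor of 3 counts over the group; with 1 to 3 counts the ratio is given with an exact 95% interval, which covers counting error alone and not differences between rats.

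Alternatives were median-of-ratios factors, library totals, scaling without muscle, blood and mitochondrial genes, scaling on stromal lists (chosen after the muscle share was seen), DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1), no filter and a stricter filter, a replicate block, the muscle or adipocyte list level as a covariate, and leaving out each library. Figures and tables were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.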

Results

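RNA-seq profiles were collected from the synovium, the soft tissue that lines the joint, of 7 male rats aged 3 months. In 4 rats, MIA had been injected into the right knee joint at 10 mg per kg in 0.1 mL. The labels do not spell MIA out; in knee osteoarthritis models the abbreviation usually stands for monosodium iodoacetate, an inhibitor of glycolysis. The other 3 rats were left untreated and carry the numbers 2, 3 and 4 in the labels. The MIA rats carry the numbers 1 to 4. Tissue was taken 4 weeks after injection, with 1 library per rat. The comparison of MIA with control asks how the synovial transcriptome of the injected joints differed from that of untreated joints. The table gave 20660 genes, and total counts ran from 13870822 in control 3 to 16261089 in MIA 4. Between 13126 and 14335 genes per library had at least 10 counts.

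The libraries differed in the tissue transcripts they held. Genes of the skeletal muscle list took 14.5% ± 1.35 (SD, n = 3) of the counts in control libraries and 2.54% ± 1.96 (SD, n = 4) in MIA libraries, with 2.43%, 0.0643%, 4.86% and 2.81% in MIA 1 to 4. The collagen list took 0.694% ± 0.241 (SD, n = 3) and 8.86% ± 1.99 (SD, n = 4), and the adipocyte list 0.220% ± 0.0311 and 0.105% ± 0.0352. Each of these 3 shares had every MIA library on one side of every control library, and the exact two-sided permutation p of 0.0286 is the smallest that 35 assignments of the labels can give (0.0571 after Benjamini-Hochberg adjustment over 6 shares). Mitochondrially encoded genes took 12.5% ± 1.09 and 8.76% ± 2.04, and blood genes 0.788% ± 0.415 and 1.43% ± 1.18, with exact two-sided permutation p of 0.0857 (adjusted 0.103) and 0.4 (adjusted 0.4). The muscle share is given again beside the gene groups that moved with it.

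**Figure D1:**
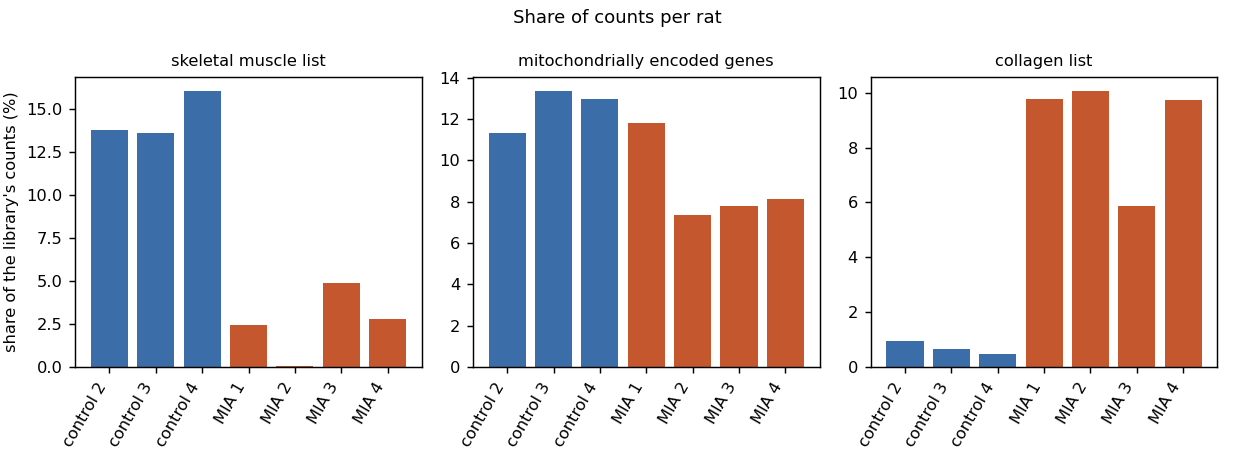
Share of each library's counts (%, vertical axis) taken by the skeletal muscle list, the mitochondrially encoded genes and the collagen list, 1 bar per rat, control in blue and MIA in orange. The muscle share was at least 13.6% in each control library and at most 4.86% in each MIA library, while the collagen share was at most 0.944% and at least 5.88%.

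Expression of 14054 genes was compared, and 5751 differed between MIA and control at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 2998 of them higher and 2753 lower in MIA. A change of at least 2-fold was found for 3993 genes, 2187 higher and 1806 lower. The first principal component carried 65.2% of the variance and separated all MIA libraries from all control libraries. Correlations of log2 expression between libraries ran from 0.963 to 0.976 among controls, from 0.873 to 0.951 among MIA libraries and from 0.726 to 0.889 between the groups. Among the tested genes, 49.2% had groups that did not overlap, against 5.71% by chance. The balance of directions depended on scaling: with library totals 5259 genes were higher and 1477 lower (78.1% higher, against 52.1%), and the median log2 change of all genes moved from 0.07 to 0.51. With factors from stromal gene lists 37.2% of the calls were higher and the median was −0.17. With limma on log2(FPKM + 1) 75.5% were higher. With the muscle list level as a covariate 1901 genes were called and with the adipocyte list level 2839, while leaving out control 3 or control 4 left 3628 and 3399.

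The genes with the largest changes included enzymes and structural proteins of cartilage and matrix. Fbn2, a fibrillin of elastic microfibrils, was 244-fold higher (ENSRNOG00000043219; log2 change 7.93 ± 0.46 SE, adjusted p = 0.000232), from 0.197 ± 0.21 CPM (SD, n = 3) to 47.7 ± 7.04 CPM (SD, n = 4). Acan, the core protein of the cartilage proteoglycan aggrecan, was 218-fold higher (7.77 ± 0.92, adjusted p = 0.0012). The macrophage elastase Mmp12 (10.00 ± 2.21, adjusted p = 0.00891) and the cartilage collagen Col2a1 (9.19 ± 2.31, adjusted p = 0.0147) had the largest log2 changes, but MIA 2 alone held 863 CPM of Mmp12 and 924 CPM of Col2a1, against at most 124 and 122 CPM in the other MIA libraries. Atp6v0d2, a proton pump subunit of osteoclasts, rose from 1 count in the 3 controls to 622 counts, a ratio of 337 with an exact 95% counting interval from 60.3 to 13343. Gbx2, a homeobox gene, and Ly6l were not counted in any control; against a floor of 3 counts over the group they were at least 25.3-fold and 21.7-fold higher. Without any one control the adjusted p of Col2a1 lay between 0.0517 and 0.0643, and Atp6v0d2 reached 0.0514 without control 3 and 0.0502 without control 4. With limma-voom, the adjusted p was 0.264 for Mmp12, 0.367 for Col2a1 and 0.117 for Atp6v0d2. The muscle covariate also ended these calls, for Mmp12 at 6.30 ± 1.76 (adjusted p = 0.0522), Atp6v0d2 at 7.03 ± 2.13 (0.0636) and Col2a1 at 2.49 ± 1.45 (0.264). That covariate, the muscle list level, was 2.88 log2 CPM in MIA 2 and 7.57 to 9.48 in the other MIA libraries. MIA 2 also held the most Mmp12 and Col2a1, so for these genes the covariate leans on that library.

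Among the largest falls, Mrgprg, an orphan receptor of the Mas-related family, was not counted in MIA and was at least 36.3-fold lower against the same floor. Mcidas, a regulator of multiciliated cells, fell from 150 counts in controls to 1 in MIA, a ratio of 277 (exact 95% counting interval 48.9 to 10998). The cardiac and slow-muscle myosin light chain Myl2 fell by 5.63 ± 1.50 on the log2 scale (adjusted p = 0.0182), from 309.5 ± 236 to 6.21 ± 9.19 CPM. Sbk3 (−6.08 ± 1.16), Gnat3 (−6.07 ± 1.09), Tecrl (−5.97 ± 1.02) and the amylase Amy1a (−5.87 ± 0.95) fell too, with adjusted p of 0.0052 or less. These falls ran alongside the muscle-list share of 14.5% in control and 2.54% in MIA libraries, and with the muscle level as a covariate each of these genes except Mrgprg lost its call. Tecrl and Myl2 then had positive log2 changes of 1.57 and 2.24. Myl2 is itself a member of the muscle list, so its result with that list's level follows in part from the adjustment. Gnat3 (−5.54 ± 2.41), Sbk3 (−4.77 ± 2.51) and Amy1a (−3.87 ± 2.42) lost their calls with wider errors. Whether the falls of these genes follow the muscle share is therefore not shown. The value of Mcidas (−1.51 ± 33.7), with 1 count in MIA, cannot be read, because its error was derived from a very small F. The adjusted p of Myl2 was 0.0559 without control 4 and 0.0563 with the adipocyte covariate.

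Genes that build and cross-link collagen rose together in MIA synovium. Of 24 tested members of the collagen and fibril assembly list, 21 rose and none fell (22 and 0 adjusted over the list alone), with a median log2 change of 2.88. Loxl2, a collagen cross-linking oxidase (ENSRNOG00000016758), was 13.3-fold higher, from 10.7 ± 1.0 to 143 ± 24.1 CPM (log2 change 3.74 ± 0.21, adjusted p = 0.000232), and Col8a1, a short-chain collagen, was 8.99-fold higher (3.17 ± 0.24). The fibrillar collagen genes Col1a1 (4.51 ± 0.80) and Col3a1 (3.80 ± 0.68), both chosen after their values were seen, were higher as well, Col1a1 22.7-fold. Dcn, which encodes the small proteoglycan decorin and was chosen in the same way, had a log2 change of 0.16 ± 0.42 that did not pass and changed sign with the scaling. The list was higher as a whole (camera, adjusted p = 1.03e-12, preset correlation 0.01); the adjusted p = 0.405 with an estimated correlation.

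The fibrosis and TGF-beta response list had 12 of 25 members higher and 1 lower (14 and 1 adjusted over the list alone). Cthrc1, a secreted protein of matrix-producing fibroblasts, was 59.4-fold higher (5.89 ± 0.36), from 3.66 ± 1.37 to 218 ± 44.7 CPM, and the matricellular gene Postn was 22.1-fold higher (4.47 ± 0.45), from 150 ± 34.2 to 3329 ± 1052 CPM. The member that fell was Tgfb2, one of the TGF-beta ligands (−0.53 ± 0.19, adjusted p = 0.0496), chosen after its values were seen; its adjusted p rose above the threshold without any one library except MIA 2, and the change was −0.10 with library totals (adjusted p = 0.656) and −0.11 with limma on log2(FPKM + 1) (0.628). The smooth muscle actin gene Acta2, chosen after its value was seen, was at 0.08 ± 0.39 and changed sign with the scaling. Of 26 matrix protease and inhibitor genes, 22 rose and 1 fell (22 and 1 adjusted over the list alone). Adamts7, a metalloprotease that cleaves cartilage oligomeric matrix protein, was 6.68-fold higher (2.74 ± 0.19), and stromelysin Mmp3 8.68-fold higher, from 36.7 ± 5.53 to 319 ± 45.9 CPM (3.12 ± 0.23). The single fall was in the protease inhibitor gene Timp4 (−3.12 ± 0.28, adjusted p = 0.000842), chosen after its values were seen. Camera called both lists higher (adjusted p = 9.92e-05 for fibrosis and 9.36e-09 for proteases), with adjusted p = 0.509 and 0.293 with an estimated correlation.

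Many of the cytokine, chemokine and inflammasome genes tested were higher in MIA, with wide differences between the MIA rats. Of 27 cytokine and chemokine genes 16 rose and none fell (16 and 0 adjusted over the list alone): the cytokine Il6 was 50.8-fold higher (5.67 ± 0.94, adjusted p = 0.00306), from 0.369 ± 0.107 to 19.2 ± 16.9 CPM, and osteopontin (Spp1) 31.4-fold higher (4.97 ± 0.83). Spp1 was at 1222 CPM in MIA 2 and at 176 to 400 CPM in the other MIA libraries. On the inflammasome and pyroptosis list 12 of 22 rose and 1 fell (13 and 1 adjusted over the list alone). Tlr2, a receptor for bacterial lipoproteins and matrix fragments, rose by 2.34 ± 0.36, and Txnip, a thioredoxin-binding protein that can activate the inflammasome, fell by 1.88 ± 0.29. The camera test called both lists higher (adjusted p = 0.00298 and 0.0314), with adjusted p = 0.405 and 0.618 with an estimated correlation. The cytokine list was at an adjusted p of 0.0691 with library totals, and the inflammasome list at 0.113 with library totals, 0.11 with the muscle covariate, 0.0735 with the adipocyte covariate and 0.0516 without control 2. Cytokine genes that rose numbered 9 with limma-voom, 8 with the muscle covariate and 5 with the adipocyte covariate, and inflammasome genes 6 with stromal scaling, 7 with limma-voom, 5 with the muscle covariate and 2 with the adipocyte covariate. The median log2 change of the cytokine list was 2.28, and 2.98 and 2.32 with these covariates, and that of the inflammasome list 1.05, and 0.90 and 1.01, so calls were lost with medians of similar size. Il6 was at 5.11 ± 1.92 with limma-voom (adjusted p = 0.0677). Without control 3 or control 4 the count of cytokine genes that rose was 8 in each case; the inflammasome count was 7, 7 and 4 without control 2, 3 and 4.

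Complement had 9 of 21 genes higher and none lower (9 and 0 adjusted over the list alone): C7, a component of the membrane attack complex, rose 3.49-fold (1.80 ± 0.28) and the classical pathway protease C1s 2.66-fold (1.41 ± 0.23), while the list as a whole was not called (camera adjusted p = 0.0702). Without control 3 or control 4 the number that rose was 5, without MIA 2 3 of its genes were lower, and without MIA 4 the list was called (adjusted p = 0.0393), as it was with the adipocyte covariate (0.023). With stromal scaling 5 of its genes rose. With the muscle or adipocyte covariate 3 rose, at median changes of 0.27 and 1.02, against 0.69. The interferon response list had 1 of 25 genes higher, Stat2, a transcription factor of the interferon pathway (0.64 ± 0.21, adjusted p = 0.0417), and none adjusted over the list alone. The count depended on the scaling, with 8 of 25 higher with library totals and with limma on log2(FPKM + 1), and 0 with stromal scaling. Leaving out any one library other than control 3 ended the call of Stat2, with adjusted p from 0.0513 to 0.152, and it was 0.285 with stromal scaling, 0.278 with the muscle and 0.293 with the adipocyte covariate. Psmb8, an immunoproteasome subunit, had a log2 change of 0.72 ± 0.28 that did not pass (adjusted p = 0.0689) but did with library totals (0.0206). The interferon list had a camera adjusted p of 0.0702, which was 0.00217 without control 3, 0.0367 without MIA 1 and 0.0242 without MIA 4; 3 of its genes rose without control 3.

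Markers of several immune cell types were higher. Macrophage genes rose in 11 of 14 cases and fell in none (11 and 0 adjusted over the list alone), among them the lipopolysaccharide co-receptor gene Cd14, 4.37-fold (2.13 ± 0.33). Of 14 antigen presentation and dendritic cell genes 11 rose (12 adjusted over the list alone), among them RT1-Da, a class II chain, 4.69-fold (2.23 ± 0.34); its counts may be shared with near-identical class II genes. Of 11 T and NK cell genes 6 rose (11 adjusted over the list alone), with Cd8b, a co-receptor chain of cytotoxic T cells, 23.5-fold higher (4.56 ± 0.97). Camera called these 3 lists higher (adjusted p = 0.000844, 0.00117 and 0.0184), and each had an adjusted p = 0.618 with an estimated correlation. With the muscle or the adipocyte covariate 2 macrophage genes rose, and 5 or 7 antigen presentation genes, at median changes of 1.24 or 1.77 (1.71 without a covariate) and 1.79 or 2.22 (2.14). The T and NK call ended with library totals (adjusted p = 0.156) and with the adipocyte covariate (0.0861), where Cd8b was at 3.45 ± 1.41 (0.12), and its count was 3 without control 3, 3 without control 4 and 10 without MIA 4. Of 8 neutrophil genes 5 rose (6 adjusted over the list alone), with Csf3r, the receptor for granulocyte colony-stimulating factor, at 3.34 ± 0.95. MIA 3 held 105 CPM of Csf3r, against 7.34 to 27.5 CPM in the other MIA libraries. Its neutrophil list level was 4.72 on the log2 CPM scale, against 1.53 to 2.25. Of 9 B and plasma cell genes 3 rose (5 adjusted over the list alone), with Sdc1, a proteoglycan that plasma cells and other cells carry, 7.47-fold higher (2.90 ± 0.45). Neither list was called by camera (adjusted p = 0.199 and 0.0745), although the B and plasma cell list was called without MIA 1 (0.0487), without MIA 2 (0.0484) or without MIA 3 (0.0487) and with the muscle covariate (0.0213). Both lists were called with stromal scaling (neutrophil 0.0366, B and plasma cell 0.025). With limma-voom 0 neutrophil genes and 1 T and NK gene rose; library totals gave 11 T and NK genes. The neutrophil count was 1 without control 2 and 0 without control 3 or control 4, the adjusted p of Csf3r lay between 0.0756 and 0.0808 without any one control and was 0.151 with limma-voom and 0.446 with the adipocyte covariate, and the B cell count was 1 without control 3 or control 4.

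Cell division genes rose: 22 of 24 were higher and none lower (23 and 0 adjusted over the list alone), with a median log2 change of 3.94. Cyclin A2 (Ccna2) was 34.8-fold higher (5.12 ± 0.63, adjusted p = 0.00135), from 0.398 ± 0.0809 to 14.1 ± 9.85 CPM, and the proliferation marker Mki67 24.1-fold higher (4.59 ± 0.57), from 1.55 ± 0.836 to 37.8 ± 21.8 CPM. MIA 1 had the highest level of this list, 4.90 on the log2 CPM scale against 3.33 to 3.58 in the other MIA libraries. Camera called the list higher (adjusted p = 6.75e-07), with an adjusted p = 0.618 with an estimated correlation. With the adipocyte level as a covariate 12 members rose, at a median change of 2.92.

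Fibroblast, skeletal and signalling lists moved in part. The sublining fibroblast list had 6 of 11 genes higher and none lower (7 and 0 adjusted over the list alone), led by the surface protein gene Thy1, with a log2 change of 3.46 ± 0.40, and camera called it higher (adjusted p = 0.0238; adjusted p = 0.618 with an estimated correlation), but not with library totals (0.0827) or the muscle covariate (0.192); 3 members rose without control 3, without control 4 or with stromal scaling, and 2 with the muscle covariate. Of 12 lining fibroblast genes 4 rose and 1 fell (4 and 1 adjusted over the list alone): the secreted protease gene Htra1 rose 4.43-fold (2.15 ± 0.32), with 1381 CPM in MIA 2, and the fall was in Clic5 (−2.29 ± 0.44), a chloride channel family gene chosen after its values were seen. Camera did not call this list (adjusted p = 0.506), its median change was 0.04, and 3 members fell without MIA 2. With stromal scaling the median was −0.31. The factors of that scaling come from this list and the sublining list, among others, so it does not test their changes. Of 15 chondrocyte genes 5 rose (5 adjusted over the list alone), among them the fibrillar collagen gene Col11a1, 50.1-fold (5.65 ± 0.67). Of 13 osteoblast and osteoclast genes 6 rose (6 adjusted over the list alone), among them the osteoblast transcription factor gene Runx2, 4.76-fold (2.25 ± 0.26). The Wnt and BMP list had 10 of 32 genes higher and 4 lower (11 and 5 adjusted over the list alone), with the Wnt receptor gene Fzd1 4.03-fold higher (2.01 ± 0.14) and the ligand gene Wnt11 4.95-fold lower (−2.31 ± 0.29). The last 3 lists were not called by camera (adjusted p = 0.199, 0.0955 and 0.506). The chondrocyte count was 3 without any one control, and that of the bone list was 3 without control 3, control 4, MIA 3 or MIA 4, while without MIA 1 the bone list was called (adjusted p = 0.026). With stromal scaling both lists were called higher (chondrocyte 0.0167, bone 0.012), and with limma-voom 3 genes of each rose. The Wnt and BMP counts of rises were 6 and 5 without control 3 and control 4, and its falls were 2 without any one control or MIA 1.

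Mitochondrial energy genes fell together, in libraries that also held less muscle RNA. Each of the 28 tested genes of oxidative phosphorylation and the citrate cycle was lower in MIA (28 adjusted over the list alone), with log2 changes from −2.13 to −1.18 and a median of −1.89. Idh3a, a citrate cycle dehydrogenase subunit, was 3.99-fold lower (adjusted p = 0.00161), from 365 ± 46.6 to 91.5 ± 27.2 CPM, and Sdha, of complex II, 4.32-fold lower (−2.11 ± 0.29). Camera called the list lower (adjusted p = 5.77e-12), with an adjusted p = 0.618 with an estimated correlation. The muscle list took 14.5% of the counts in control and 2.54% in MIA libraries. With its level as a covariate 7 of the 28 genes were called lower, at a median change of −1.10. Camera still called the list lower there (adjusted p = 1.23e-09), but with the preset correlation. The correlation estimated for this list, without the covariate, was 0.851. In models chosen later, with the muscle share instead, the MIA effect was 0.81 ± 1.16 on the list level. On the list's mean CPM it was 72.1 ± 252. A fall beside the lower muscle share is therefore not shown.

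Glycolysis genes split, with 10 of 20 lower and 6 higher (12 and 6 adjusted over the list alone). Gpi, glucose-6-phosphate isomerase, was 2.88-fold lower (−1.52 ± 0.26) and the lactate dehydrogenase subunit gene Ldhb 12.6-fold lower (−3.66 ± 0.65). With the muscle covariate they were at −1.30 ± 0.38 and −2.67 ± 0.89 and no longer passed (adjusted p = 0.0564 and 0.0788), with wider errors. The list was not called by camera (adjusted p = 0.1) but was without MIA 2 (0.0201) and with library totals (0.0133). With the muscle covariate 1 of its genes fell and 0 rose, although the enolase gene Eno1, chosen after its values were seen, was at 1.15 ± 0.42 (adjusted p = 0.0997), against 1.25 ± 0.29. The number that rose was 2 without control 4, and 3 without MIA 2 or MIA 4. On the skeletal muscle list 5 of 21 genes passed, all lower (0 adjusted over the list alone), among them the carbonic anhydrase gene Car3 (−3.08 ± 0.77, adjusted p = 0.0143), from 6091 ± 3177 to 718 ± 596 CPM. The list had a median change of −3.03 and was called lower (camera adjusted p = 0.000511, and 0.618 with an estimated correlation). The muscle covariate is the level of this same list, so it does not test the members, Car3 included. Its count was 11 with stromal scaling, 14 with DESeq2 and 9 with limma on log2(FPKM + 1), and it depended on single libraries, with 20 genes lower without MIA 2, 2 without control 3, 0 without control 4, 2 without MIA 1 and 3 without MIA 3, and the adjusted p of Car3 was 0.0535 without control 4, 0.203 with the muscle covariate and 0.0721 with the adipocyte covariate.

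The hypoxia response list had 5 of 23 genes higher and 8 lower (5 and 8 adjusted over the list alone), and its median of −0.24 was 0.18 with library totals. The MYC antagonist gene Mxi1 was 2.92-fold lower (−1.55 ± 0.16) and Egln1, a prolyl hydroxylase that marks HIF-1alpha for degradation, 3.17-fold lower (−1.67 ± 0.19). Hif1a itself (2.45 ± 0.30) and the heme oxygenase gene Hmox1 (4.12 ± 0.76), both chosen after their values were seen, were 5.46-fold and 17.4-fold higher. Vegfa, on the same list and chosen in the same way, was 3.78-fold lower (−1.92 ± 0.44, edgeR adjusted p = 0.0102). It lost its call with the muscle covariate (−1.59 ± 0.73, adjusted p = 0.169). On the ferroptosis and oxidative stress list 5 of 22 rose and 3 fell (5 and 3 adjusted over the list alone), and its median of 0.08 was −0.17 with stromal scaling, where 1 rose, against 10 with library totals. Catalase (Cat) was 2.86-fold lower (−1.51 ± 0.19) and Keap1, the sensor that holds back the NRF2 pathway, 2.16-fold lower (−1.11 ± 0.14). Neither list was called by camera (adjusted p = 0.413 and 0.93). The muscle share fell in the same libraries; with its level as a covariate 2 hypoxia genes rose and 4 fell, and 0 ferroptosis genes rose. Errors were wider there: the ferritin gene Ftl1, chosen after its values were seen, was at 1.24 ± 0.44 (adjusted p = 0.0927), against 1.44 ± 0.30. Hypoxia genes that rose numbered 3 without control 4, those that fell 5 without control 3, and ferroptosis genes that rose 3 without any one control.

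On the nociception and nerve growth list 8 of 17 genes rose and 2 fell (8 and 2 adjusted over the list alone), and camera did not call it (adjusted p = 0.145). Bdkrb1, the inducible bradykinin receptor, went from 2 counts in controls to 90 in MIA, a ratio of 24.4 (exact 95% counting interval 6.56 to 205), while the axon guidance gene Ntn1 was 4.43-fold lower (−2.15 ± 0.34). The other fall was in the neurotrophin gene Bdnf (−2.07 ± 0.64, adjusted p = 0.0314), chosen after its values were seen, and its adjusted p was 0.119, 0.102, 0.0586 and 0.0587 without control 3, control 4, MIA 1 and MIA 2. The number of rises was 5 without control 3 or control 4, 3 with the muscle covariate and 4 with the adipocyte covariate, at median changes of 0.77 and 1.30, against 0.85.

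Of 11 endothelial genes 1 rose, the leukocyte adhesion gene Sele (1.98 ± 0.53, adjusted p = 0.0193, but none adjusted over the list alone). The list's median of 0.18 was −0.03 with stromal scaling, whose factors use this list. Of 11 pericyte and smooth muscle genes 1 rose, Rgs5, a regulator of G protein signalling, and 2 fell, the potassium channel partner Abcc9 (−1.25 ± 0.19) and the intermediate filament gene Des (1 and 2 adjusted over the list alone); the median of −0.21 was 0.23 with library totals. Des is also a muscle gene and went from −2.82 ± 0.67 to −0.90 ± 0.43 with the muscle covariate (adjusted p = 0.19), while Abcc9 was at −0.90 ± 0.25 (adjusted p = 0.0523). Of 18 adipocyte genes 4 fell and 1 rose (3 and 1 adjusted over the list alone), with the lipid droplet gene Plin4 10.1-fold lower (−3.34 ± 0.35), from 340.3 ± 90.7 to 33.6 ± 11.9 CPM, next to the lower muscle and adipocyte shares of the MIA libraries. The gene that rose was the fatty acid synthase gene Fasn (1.36 ± 0.38), which lost its call without control 3 (adjusted p = 0.0847) or control 4 (0.0911). The adipocyte list was not called by camera (adjusted p = 0.0702) but was called lower without control 3 (0.00285) or MIA 2 (0.0274), with library totals (0.00868), with stromal scaling (0.0292) and with the muscle covariate (0.00981). The number of its genes that fell was 10 with stromal scaling and 9 with DESeq2. Rgs5, Des and Fasn were chosen after their values were seen.

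Of 12 nerve and Schwann cell genes Erbb3, a neuregulin receptor, rose (1.11 ± 0.30, adjusted p = 0.0184) and the myelin gene Mag fell (−2.25 ± 0.73, adjusted p = 0.0383), with none adjusted over the list alone. With stromal scaling 5 fell, and with library totals 3 rose and 0 fell. Of 8 mast cell genes the receptor gene Kit rose (1.14 ± 0.28, adjusted p = 0.0135) and the transcription factor gene Gata2 fell (−1.12 ± 0.34; 1 and 1 adjusted over the list alone). None of 9 blood and erythroid genes passed (0 adjusted over the list alone), and the platelet gene Pf4 was at 1.46 ± 0.53 (adjusted p = 0.0553; 0.00265 without MIA 4). Of 17 immediate early and handling stress genes 4 fell and 1 rose (4 and 1 adjusted over the list alone), with the transcription factor gene Jun 2.66-fold lower (−1.41 ± 0.21); the rise was in Junb (1.16 ± 0.37), with 4 rises with library totals and 5 with limma on log2(FPKM + 1), and the median of 0.27 and the mean of −0.24 had opposite signs. Camera called none of the nerve, mast cell, blood and stress lists (adjusted p = 0.422, 0.312, 0.657 and 0.657), nor the endothelial and pericyte lists (0.423 and 0.657). Without control 3 or control 4 the calls of Sele, Kit, Erbb3, Mag and Junb ended, Junb also lost its call without MIA 1 or MIA 4. Gata2 lost its call without control 2, control 3 or MIA 1. With the muscle covariate the adjusted p was 0.258 for Kit and 0.106 for Erbb3, with stromal scaling 0.058 and 0.0863, and with the adipocyte covariate 0.0565 for Sele. On these lists 3 mast cell genes rose without MIA 1, and 2 stress genes fell without control 3. Mag, Gata2 and Junb were chosen after their values were seen.

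As a whole, camera called 12 of 31 lists, 10 higher and 2 lower, and 0 with an estimated correlation, where the smallest adjusted p were 0.293 for matrix proteases and 0.405 for collagens and for cytokines. At least 12 lists were called in 18 of the 35 ways to split the 7 libraries into 3 and 4, the real one included. Fry, which asks whether a list's genes move one way and does not compare them with other genes, called 11. These were not all the same lists. Fry did not call skeletal muscle (fry adjusted p = 0.144), T and NK cell (0.118) or inflammasome (0.0599). It called glycolysis and nociception (0.0372 for each), which camera did not. The mean level of each list per library was tested by exact two-sided permutation of the 7 labels; the smallest p was 0.0286, the smallest that 35 assignments can give, for 9 lists, and the smallest adjusted p was 0.0984.

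**Figure D2:**
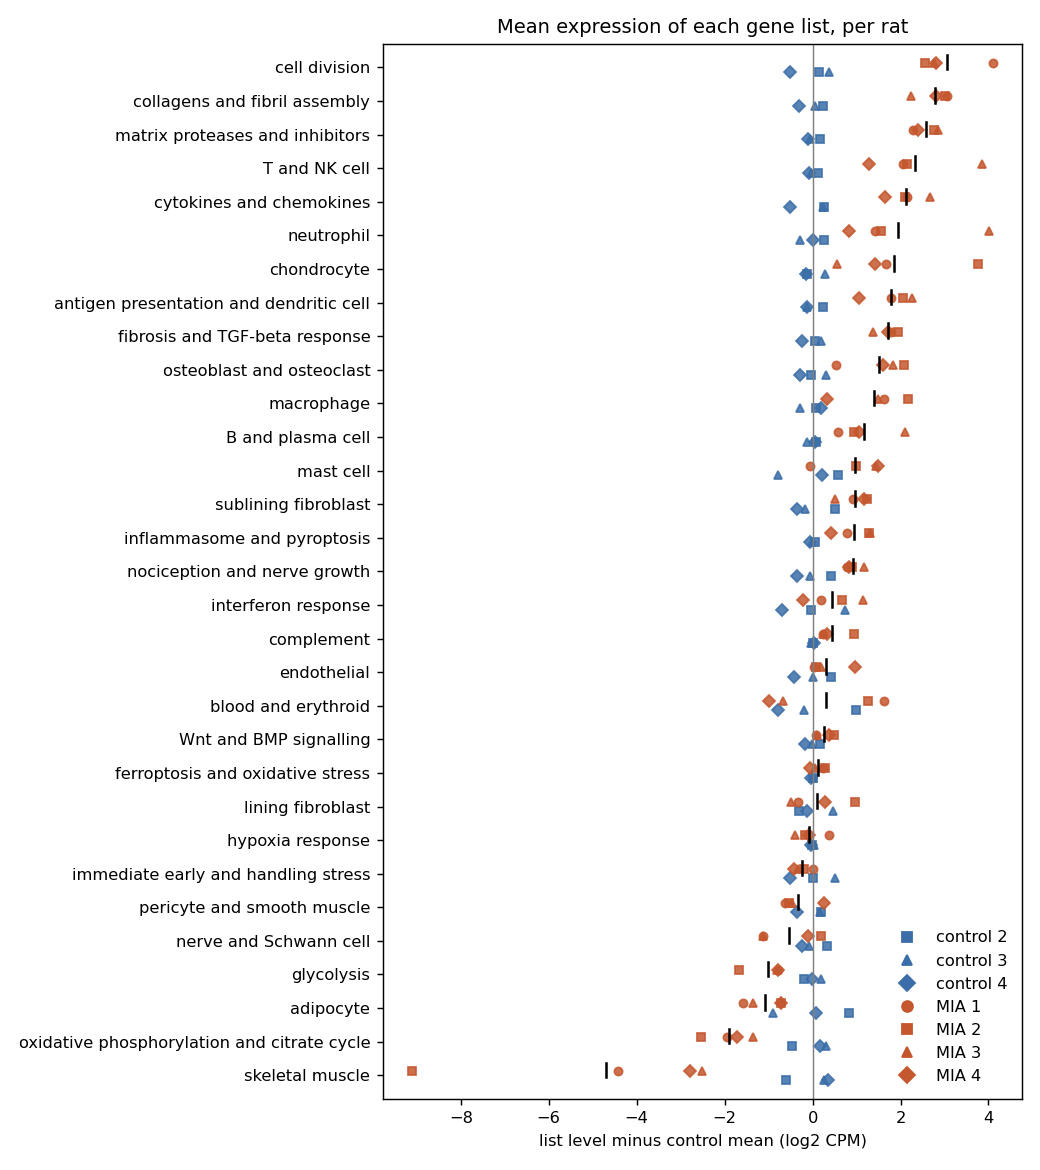
Mean log2 CPM of the tested genes of each list minus the mean of the 3 control libraries (horizontal axis), 1 symbol per rat with control in blue and MIA in orange, and a black line at the MIA mean. The cell division list stood 3.05 above control and the skeletal muscle list 4.71 below it, with MIA 2 apart from the other MIA libraries on the muscle list.

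**Figure D3:**
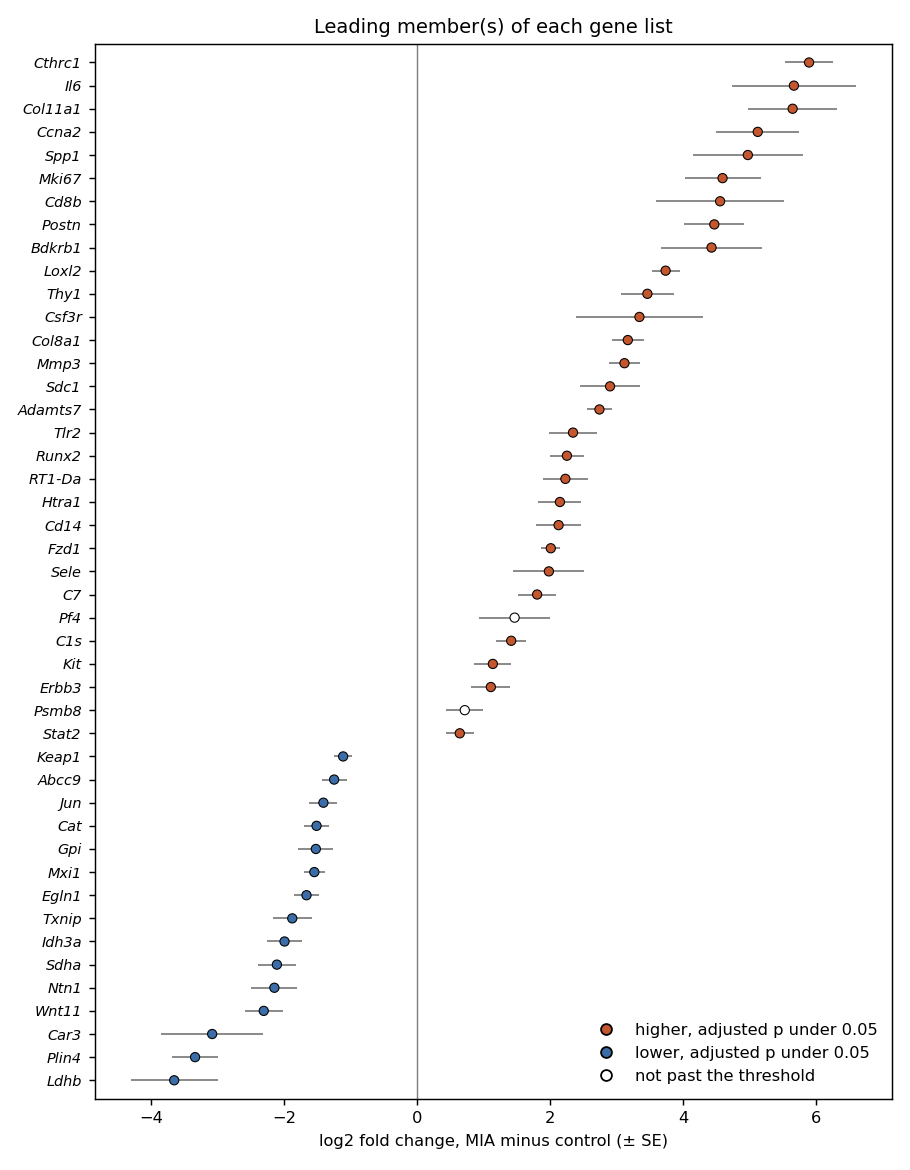
Log2 fold change of MIA against control (horizontal axis) with its standard error for the leading genes of each list, filled where the adjusted p was under 0.05. Cthrc1 rose by 5.89 ± 0.36 and Ldhb had the largest fall of this set, −3.66 ± 0.65; Psmb8 and Pf4 did not pass.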

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

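In 15 of 97 sets of 4 MIA values, 1 library lay far from the other 3; chance gives about 1 in 20. The 3 control libraries are too few for this test. The cause was not tested for any of them.

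MIA 2 had 863 CPM of Mmp12 (others 5.54 to 124), 924 CPM of Col2a1 (others 2.22 to 122) and 1381 CPM of Htra1 (others 804 to 845), a complement list level of 6.99 log2 CPM (others 6.29 to 6.37) and a glycolysis list level of 5.81 (others 6.67 to 6.69). MIA 1 had the highest cell division level, 4.90 (others 3.33 to 3.58), with 28.8 CPM of Ccna2 (others 7.85 to 10.3) and 70.4 CPM of Mki67 (others 24.0 to 28.6), and 58.2 CPM of Fbn2 (others 43.7 to 44.9).

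MIA 4 had an endothelial list level of 7.73 (others 6.80 to 6.96), 249.9 CPM of Mmp3 (others 337 to 345), 0.475 CPM of Amy1a (others 0 to 0.0638) and 0.0528 CPM of Mcidas (0 in the others), which is 1 count. In MIA 3 the collagen list took 5.88% of the counts (others 9.73% to 10.1%), and Psmb8 was at 60.9 CPM (others 32.3 to 36.7).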

How the results depend on the processing

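None of the 5751 called genes was called in the opposite direction under any setting run. Of 1107 values of the 59 genes named by rule, 1042 kept direction and side of the threshold, 57 no longer passed, 6 newly passed and 2 changed sign: with the muscle covariate Tecrl was at 1.57 and Myl2 at 2.24. Myl2 is on the list whose level is this covariate, so its change of sign follows in part from the adjustment. Library totals gave 5259 genes higher and 1477 lower, limma on log2(FPKM + 1) 4959 and 1608, and stromal scaling, chosen after the muscle share was seen, 1527 higher; these settings move the median of all genes, which was 0.07, to 0.51, 0.36 and −0.17. The muscle covariate left 1901 genes (1077 higher, 824 lower, 1797 at least 2-fold) and the adipocyte covariate 2839 (1219, 1620 and 2589); the cause was not tested.

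Leaving out each library gave 3399 to 5724 genes, 1642 to 2937 higher, 1757 to 2787 lower and 2771 to 3975 at least 2-fold, with the lowest without control 4 and the next without control 3 (3628), where 2 controls remain; lists ran from 11 to 15. Camera called 19 lists with a replicate block, the 12 and also interferon, glycolysis, neutrophil, B and plasma cell, adipocyte, chondrocyte and bone, and 0 with an estimated correlation, where fry called 11. The replicate block left out MIA 1, which has no control of the same number, and gave 4449 genes. Leaving out MIA 1 without a block gave 4770 genes and 15 lists, so the shift does not come from the block alone. Deviations of libraries with the same number correlated at 0.245, 0.0967 and 0.0425, and control 4 correlated best with MIA 3 (0.186), so the numbers were not taken as pairs. DESeq2 gave 6425 genes, limma-voom 5271, no filter 5415 and the stricter filter 5185. The alternatives planned for a table of FPKM alone were not run, because counts were present. In the simulation 15% of 2-fold changes were called. Only 98 genes were called there, against 5751 in the data, so its Benjamini-Hochberg cut-off was stricter. The 15% therefore does not measure how many small changes were missed in these data.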

Other observations

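The 6 genes with roles in hyaluronan, the main polysaccharide of joint fluid, that follow were chosen after their values were seen to be higher in MIA; no list of such genes was fixed or tested, so they do not speak for the group. The synthase gene Has2 rose by 4.43 ± 0.72 on the log2 scale, and the hyaluronan-degrading Cemip by 4.95 ± 0.71. Tnfaip6 (4.53 ± 0.48) and Ptx3 (4.51 ± 0.81), whose products cross-link hyaluronan matrices, the binding proteoglycan gene Vcan (3.23 ± 0.39) and the receptor gene Cd44 (2.15 ± 0.30) rose too. These calls held in all alternatives run, except that of Has2 with the adipocyte covariate (adjusted p = 0.052). The lubricin gene Prg4 was at −0.42 ± 0.97, did not pass, and changed sign with the scaling.

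The tests of scaling and dilution below were chosen after the results were seen, as were all models that use the muscle share. The bound for cartilage or bone was set after the list levels were seen. The clock output genes Tef (−2.24 ± 0.19) and Usp2 (−3.34 ± 0.23), chosen after their values were seen, fell. Of 7 genes of the Dbp arm, which holds neither, 5 fell, and Nr1d1 (adjusted p = 0.154) and Per2 (0.0599) did not pass; the 3 genes of the Arntl arm rose, Clock by 0.42, Arntl by 0.88, and Npas2 by 2.30. The Arntl call ended without control 2 (0.0883), control 3 (0.0888) or MIA 1 (0.0512), with the muscle covariate (change 0.47, adjusted p = 0.396), the adipocyte covariate (0.175) and stromal scaling (change 0.60, 0.248). The genes named from the arms lie outside the naming rule and were chosen after the values of Tef and Usp2 were seen. The Arntl arm minus the Dbp arm was 2.53 higher in MIA, as collection at another time of day may give, and the hours of collection are not in the labels. With the muscle level in the model this difference was 2.40 ± 0.43, and 3.28 ± 1.28 with the share. The bound set beforehand against less muscle was met with the level but not with the share. The level model argues against less muscle as the whole cause, while the share model, with its wider error, does not settle it. A change of the clock in MIA tissue stays open as well.

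The fall of oxidative phosphorylation transcripts, and of the 10 glycolysis genes that fell, may come from less muscle in the MIA tissue; the glycolysis list was split and not called. Over 6 pairs (Cox7a1 and Cox7a2 were not tested), muscle isoforms changed by a median of −4.15 relative to their partners, and the partners rose by a median of 1.258. The glycolysis partners Pgam1 (1.36), Eno1 (1.25) and Pfkl (1.27) rose, which argues against a fall of glycolysis transcripts in every cell type. The carrier Slc25a5 was at 1.39. The only respiratory chain partners were Cox6a1 (0.72) and Cox8a (0.33, edgeR adjusted p = 0.244), so the pairs do not decide this for oxidative phosphorylation. Less muscle by itself also leaves a larger share to the partners. With library totals 26 oxidative phosphorylation members were still lower, against scaling as the cause for that list. With the muscle level in the model the oxidative phosphorylation list was lower by 1.11 (−1.11 ± 0.31), which met the bound set beforehand for a fall in other cells, but a linear model with the share, added after that result was seen, gave 72.1 ± 252 CPM, so a fall in other cells beside the muscle share cannot be told apart from muscle alone. Loss of muscle by dissection or by disease was not tested.

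The rise of collagen, protease and division genes was larger than a dilution that raises all other tissue alike would give. The smallest of 9 differences from lining, endothelial and pericyte lists was 2.26, and the smallest from the lining list was 2.47. A loss of muscle that also lowers the lists compared was not tested. Without MIA 2, which held the most Col2a1, the collagen level still rose by 2.70. This met the bound set against cartilage or bone, which also put a limit on Col2a1, Bglap, Ibsp and Dmp1 that was met. The bound named MIA 2 as the library with the highest chondrocyte list, so it was set after the list levels were seen. Dmp1 was at 2.76 to 12.3 CPM in MIA (controls 2.46 to 6.43). Leaving out MIA 2 alone does not remove them: Col2a1 was at 122 CPM in MIA 1 (controls at most 0.561), and Ibsp was at 9.40 to 30.4 CPM in MIA (controls at most 3.79). But Col2a1 ran from 2.22 CPM in MIA 3 to 924 in MIA 2, and Bglap was above its highest control (5.37) only in MIA 4 (16.2), while the collagen share was 5.88% to 10.1% in MIA and at most 0.944% in controls. Acan (64.2 to 455 CPM in MIA, controls at most 2.55) and Col11a1 (125 to 694 CPM, controls at most 7.85) were high in every MIA library. The uneven Col2a1 and Bglap speak against cartilage or bone as the cause of the whole collagen rise, but Acan and Col11a1 do not. Cartilage or bone as a cause of the whole rise or a part therefore stays open, and proteases and division were not tested for it. With the muscle level in the model the changes were 2.41 ± 0.37, 2.44 ± 0.29 and 3.25 ± 0.81, and with the share, which follows the groups, 0.66 ± 0.75, 2.11 ± 0.88 and 2.01 ± 2.39. In the model with the share, the collagen and division rises cannot be told apart from less muscle. Altered fibroblasts or new cells in MIA tissue are a hypothesis that stays open.

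Of the 35 splits of the 7 libraries into 3 and 4, 1 (the real one) gave as many genes as the 5751 called (highest other 48). The same held for the 2998 higher (3), the 2753 lower (45) and the 3993 at least 2-fold (48). Splits that mix the groups hold the group difference as spread, which keeps their counts low. The share of 1 in 35 is the smallest this test can give, so it cannot exclude chance for these counts. For the 12 lists chance is not excluded either, since 18 splits gave as many (highest other 21).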
